A study of Danio rerio with 4 samples.

How the data were processed

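Binding of CTCF was measured by ChIP-seq in whole zebrafish embryos at 24 hpf (hours post fertilisation, the prim-5 stage). Per the labels' protocols, embryos came from crosses of fish carrying a tagged ctcf allele beside a wild-type one, and each biological replicate was prepared from 2000 embryos of independent crosses. Chromatin was fixed in 1% formaldehyde for 15 min, sheared to 100 to 200 bp and precipitated with an antibody against the HA epitope. The 4 samples were 2 ChIP libraries and 2 libraries of input DNA, sequenced as single-end reads of 100 bp.

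The measurement is 1 deposited list of peaks called on the combined ChIP replicates, per the file headers. The submitters' processing notes name the build danRer10 and, with no role or order, CASAVA, FastQC 0.9.3, cutadapt 1.3, Bowtie2 2.2.5, SAMtools 1.1, Picard 1.45, MACS2 and deepTools 3.0.1. The peak caller's command and threshold and the way in which replicates and input were combined are not given in the sources used here. Each peak has a start, an end, the position of its summit and a score. The deposited score is a whole number given by the authors, its scale is not stated, and it ran from 88 to 11089, so peaks were ranked by it within the list, medians are given in its own units, and no fold of it was computed. Signal, p and q were 0 for every peak. Every peak was at least 200 bp wide, no 2 peaks on a chromosome lay closer than 101 bp, and none overlapped.

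Because replicates were pooled before deposit, no value per replicate or for the input entered the results, and the sequencing depth of the libraries is unknown. The tests describe where the peaks of this list lie and do not measure the spread between embryos. Where a spread is given, it is the SD over chromosomes. The precision of a peak count covers counting error only, as exact Poisson intervals at the 95% level.

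No danRer10 sequence or gene annotation was used, and a gene table of another assembly was not mixed with the peaks' coordinates. Of 28 results planned before the data were examined, 3 could therefore be computed: the peak count, the distance between neighbouring peaks and the density on the long arm of chromosome 4. The last pair departs from the plan, which asked for ungapped sequence and shuffles outside assembly gaps. The other 25, namely 14 tests of gene lists and 11 results on gene features, motifs, repeats and Hox clusters, were not run. The rule for the genes to be named could not be applied, and of its parts only the 5 highest-scoring peaks are given. The comparisons of chromosome ends, of chromosome length and of scores were chosen after the data had been seen.

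Peaks on chromosomes 1 to 25 entered the tests. A peak was placed by its centre. Chromosome lengths were not read from a genome, so each chromosome was taken to run from its first base to the end of its last peak, and assembly gaps were not removed. Neighbour distances were set against 1000 shuffles of peak positions within each chromosome, which kept neither widths nor the smallest gap between peaks. The long arm of chromosome 4 was taken from 28 Mb to the end, as fixed beforehand. Its median 1 Mb bin was ranked among 1000 stretches of as many consecutive bins placed at random on other chromosomes. These draws came from 155 distinct and largely overlapping positions on 16 chromosomes, so a comparison with 1 stretch per chromosome, the one with the lowest median, was added. Densities within chromosomes were compared by log2 ratios per chromosome. Scores were compared by rank, as the percentage of pairs of peaks, 1 from each set on the same chromosome, in which the first outranked the second, with ties split evenly, against 50%. Both were tested over chromosomes by a two-sided sign-flip permutation test with 100000 resamples. Pearson's r of the median score depends on the score's unstated scale and Spearman's rho does not. Correlations across chromosomes used 100000 permutations with Benjamini-Hochberg adjustment over the 2 relations computed. Alternatives were the 18270 highest-scoring peaks, the 9135 highest-scoring peaks, merging of peaks within 500 bp or 10 kb, other end widths, shuffles within 1 Mb or 100 kb bins and leaving out chromosome 4. The computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, with figures drawn in matplotlib 3.10.9.

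The tests were tried on simulated peaks. Of 34829 peaks with a 2-fold higher density within 2 Mb of chromosome ends, the estimated ratio was 2.00, against 1.01 for peaks placed uniformly. An arm of chromosome 4 simulated at 0.25 of the density elsewhere was estimated at 0.244 (33890 peaks). With 20% of peaks placed beside another, the median neighbour distance was 0.839 of the shuffled one, against 0.998 for uniform peaks. The peaks of this trial had no regional differences in density, so it does not separate local clustering from such differences. For peaks with a neighbour within 2 kb the rank comparison gave 50.2% with random scores, and 61.8% against an expected 61.7% with scores raised by a known amount.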

Results

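CTCF is a zinc finger protein that binds DNA and, with cohesin, anchors chromatin loops in vertebrates. Its occupancy was mapped in zebrafish embryos at 24 hpf, when the body plan is laid out, through an HA epitope carried by a tagged ctcf allele. The 4 libraries were 2 ChIP replicates and 2 input controls. A single list called on the combined replicates held 37625 peaks in danRer10 coordinates. Of these, 36540 (97.1%) lay on the 25 chromosomes and 1085 (2.88%) on 420 unplaced scaffolds. The peaks on chromosomes covered 12.04 Mb, or 0.899% of the 1340 Mb that the chromosomes spanned to their last peaks.

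Most peaks were narrow. Their median width was 264 bp, with quartiles of 225 and 355 bp and a maximum of 4101 bp. The summit lay near the middle, at a median of 49.6% of the peak's width from its start (quartiles 42.4% and 56.8%). The authors' peak score had a median of 369, quartiles of 274 and 533 and a 99th percentile of 1327. Wider peaks scored higher across the list (Spearman's rho = 0.502 across peaks, which are not independent replicates). Scores above 2000 were held by 80 peaks.

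The highest score, 11089, belonged to a peak on chromosome 5 (826047 to 826692, summit at 826394). Next in rank were adjacent peaks on the unplaced scaffold KN149861v1, with scores of 9014 (3540 to 6580) and 8236 (6805 to 10217). The remaining 2 of the 5 highest-scoring peaks were neighbours near the distal end of chromosome 4, scoring 6466 (76319940 to 76323886) and 4499 (76325046 to 76326198). Of these 5, 3 were more than 3000 bp wide, with widths of 3041, 3413 and 3947 bp. The genes and repeats at these positions were not analysed here.

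Chromosomes differed in how many CTCF peaks they held for their length. The mean density was 27.97 ± 5.10 peaks per Mb (SD, n = 25 chromosomes). Chromosome 22 was the densest with 1561 peaks, or 39.8 per Mb, followed by chromosome 25 with 36.5 per Mb and chromosome 18 with 35.0 per Mb. Chromosome 4 was the sparsest, with 1117 peaks and 14.6 per Mb, whereas the other 24 chromosomes had at least 22.2 per Mb. Chromosome 16 carried the most peaks, 1827.

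**Figure D1:**
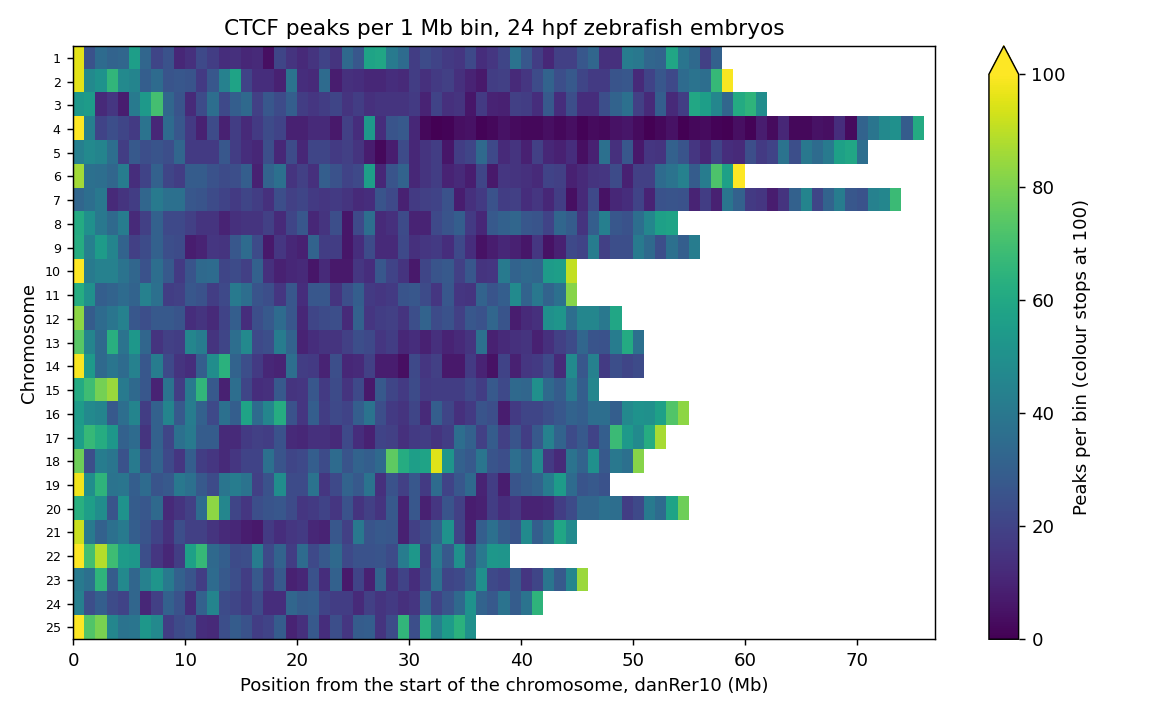
Number of CTCF peaks in each 1 Mb bin (colour) along the 25 chromosomes (rows), by position in Mb from the chromosome's start in danRer10; the last, partial bin of each chromosome is left out. Bins near chromosome ends are bright, up to 159 peaks in the first bin of chromosome 22, and a dark stretch runs from 31 to 70 Mb on chromosome 4.

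Shorter chromosomes were denser in peaks. Span and density were negatively correlated across the 25 chromosomes (Pearson's r = -0.765, permutation p = 1e-05, the smallest that the permutations can give, adjusted p = 2e-05; Spearman's rho = -0.694, permutation p = 0.00016, adjusted p = 0.00032). Without chromosomes 4 and 7, the pair farthest from the median span, r was -0.645 (permutation p = 0.00095). Without chromosome 4 alone it was -0.685. The median score of a chromosome's peaks lay between 351.5 and 388 and showed no significant relation to density (r = 0.206, permutation p = 0.322, adjusted p = 0.322; rho = 0.325, permutation p = 0.114, adjusted p = 0.114). Leaving out chromosomes 4 and 22 gave r = 0.142.

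**Figure D2:**
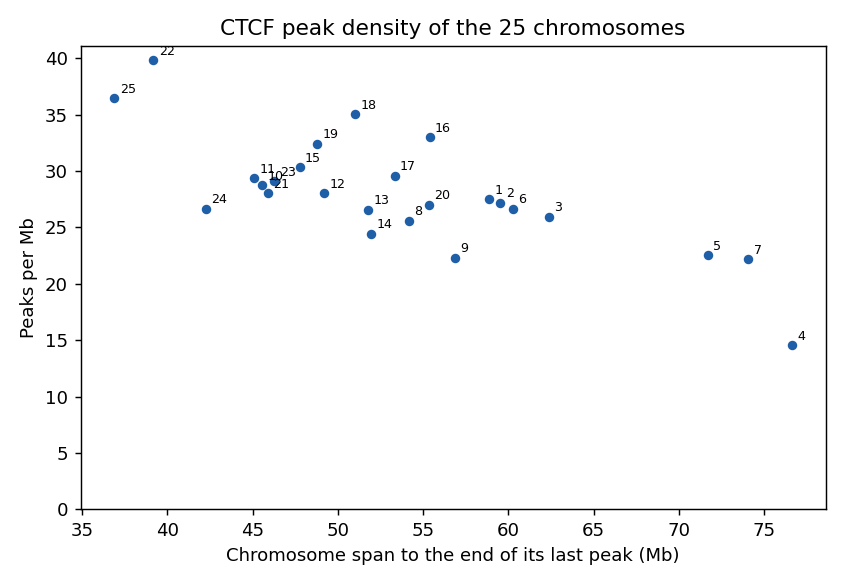
Peaks per Mb (vertical axis) against the span of each chromosome in Mb (horizontal axis, which does not start at 0); each point is 1 of the 25 chromosomes, labelled with its number. Density falls with span, from 39.8 per Mb on chromosome 22 to 14.6 per Mb on chromosome 4.

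CTCF peaks were concentrated toward the ends of chromosomes. Within 0.25 Mb of an end the density was 104 ± 35.3 peaks per Mb (SD, n = 25 chromosomes, both ends of each). It was 60.9 ± 17.6 per Mb at 0.5 to 1 Mb from the end, 48.4 ± 12.3 at 1 to 2 Mb, 29.7 ± 4.39 at 5 to 10 Mb and 19.9 ± 5.77 beyond 15 Mb. The 2 Mb at each end were 2.54 ± 0.731 times as dense as the rest of the same chromosome, and the ratio was above 1 in 25 of 25 chromosomes (sign-flip permutation test on log2 ratios, two-sided p = 2e-05, the smallest that the permutations can give). Ratios ran from 1.66 on chromosome 18 to 5.48 on chromosome 4, and without chromosome 4 the mean was 2.41 ± 0.405. The high ratio of chromosome 4 went with its sparse rest, at 11.8 peaks per Mb. Its ends held 64.75 per Mb, below the 83.5 per Mb at the ends of chromosome 22. Chromosome 18 held 55.25 per Mb at its ends and 33.3 per Mb in its rest. Left and right ends had mean ratios of 2.53 and 2.54.

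Of the 10 densest 1 Mb bins, 8 were the first of a chromosome. Bins started at the first base and the last, partial bin was left out. Left ends were therefore whole and right ends cut, so this count does not compare left with right ends. The first megabase of chromosome 22 held 159 peaks, that of chromosome 10 held 114 and that of chromosome 4 held 107. The last whole megabase of chromosome 6 (59000001 to 60000000) held 102. The median over all 1328 bins was 23 peaks (quartiles 15 and 34). Peaks within 2 Mb of an end also scored higher than those of the rest of the same chromosome, with medians of 406 and 363 over all such peaks. A peak near an end outranked a peak of the rest in 55.9 ± 2.90% of pairs (SD, n = 25 chromosomes), above 50% in 25 of 25 chromosomes (sign-flip permutation test, two-sided p = 2e-05). The medians themselves were higher near the ends in 24 chromosomes, and on chromosome 17 they were 366.5 near the ends and 367 elsewhere.

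**Figure D3:**
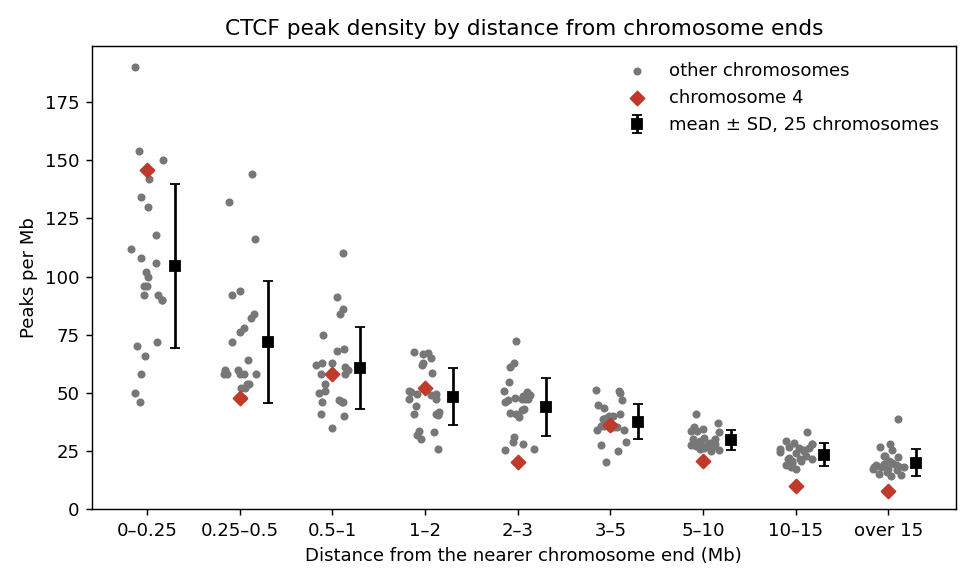
CTCF peaks per Mb (vertical axis) by distance from the nearer chromosome end in Mb (horizontal axis, classes of unequal width); points are chromosomes, with chromosome 4 as a red diamond, and black squares with bars are the mean ± SD over 25 chromosomes. The mean falls from 104 per Mb in the outermost 0.25 Mb to 19.9 per Mb beyond 15 Mb.

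Dense stretches, chosen after their values were seen, also occurred away from the ends. More than 5 Mb from either end, 1 Mb bins had a median of 20 peaks (quartiles 14 and 28, 1078 bins). The densest of them lay on chromosome 18 at 32000001 to 33000000, with 95 peaks, and chromosome 18 held 346 peaks between 28 and 33 Mb, or 69.2 per Mb. The median score of these 346 peaks was 343.5, against 372 for all peaks of chromosome 18. The next densest bins were on chromosome 20 (12000001 to 13000000, 83 peaks) and again on chromosome 18 (28000001 to 29000000, 75 peaks).

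The long arm of chromosome 4, known in zebrafish as late-replicating, heterochromatic and rich in repeats, was depleted of CTCF peaks over most of its length. From 28 Mb to the end of its last peak at 76.6 Mb it held 478 peaks, or 9.83 per Mb (95% exact Poisson interval 8.97 to 10.8, counting error only), against 27.9 per Mb elsewhere on the chromosomes, a ratio of 0.352. Its median 1 Mb bin had 3 peaks, and the lowest median among 1000 random stretches of 48 bins from 16 other chromosomes was 15 (two-sided permutation p from that rank = 0.002, the smallest that 1000 stretches can give). These stretches are not independent, since only 155 distinct positions exist. Counting 1 stretch per chromosome, the arm ranked below all 16, which gives a two-sided exact p of 0.118, the smallest that 16 chromosomes allow.

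The depletion did not cover the whole arm. Between 31 and 70 Mb there were 126 peaks, or 3.23 per Mb (95% exact Poisson interval 2.69 to 3.85, counting error only). These bounds were chosen after the values were seen. From 70 Mb to the end there were 287 peaks, or 43.4 per Mb. The same length at the right end of the other 24 chromosomes held 45.7 ± 7.65 per Mb (SD), and 13 of them exceeded chromosome 4. The first 28 Mb of chromosome 4 held 639 peaks, or 22.8 per Mb. Over the planned arm cut at 70 Mb the density was 4.55 per Mb. The median score was 333.5 between 31 and 70 Mb and 329 from 70 Mb to the end, against 369 for the peaks outside the arm.

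Stretches without any peak were longest on the same arm. All 10 intervals of more than 1 Mb between neighbouring peaks lay on chromosome 4, between 31 and 61 Mb, the longest of them from the peak ending at 57075148 to the peak starting at 59292380 (2.22 Mb between centres). None occurred in 100 shuffles of the peaks within chromosomes. These shuffles spread the peaks of chromosome 4 evenly, at 14.6 per Mb. The long intervals therefore cannot be told apart from the low density of 3.23 per Mb between 31 and 70 Mb. The longest such interval on the other chromosomes measured 0.889 Mb, on chromosome 3 between 10630215 and 11518453. All 4 of the 1 Mb bins with no peak were on chromosome 4.

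Neighbouring CTCF peaks lay closer together than random placement gives. The median distance between centres was 17520 bp, against 24817 bp in 1000 shuffles within chromosomes (two-sided permutation p = 0.002, the smallest that 1000 shuffles can give). Of 36515 neighbouring pairs, 7.14% lay within 1 kb, against 2.78 ± 0.0913% in 100 shuffles (SD), and 12.9% lay within 2 kb, against 5.48 ± 0.124%. At the other extreme, 91.2% lay within 100 kb, against 93.3 ± 0.0867%. Most of the difference in medians followed the regional density. Shuffles within 1 Mb bins gave a median of 20721 bp and shuffles within 100 kb bins 18691 bp. Both were still above the observed value (permutation p = 0.002 each). The shares above were set only against shuffles within whole chromosomes, which do not keep the regional density.

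The 5 windows of 100 kb with 30 or more peaks all lay within 2 Mb of a chromosome end. Chromosome 4 held 32 peaks between 100001 and 200000, chromosome 6 held 31 between 59900001 and 60000000, chromosome 17 held 31 between 1500001 and 1600000, and the first 100 kb of chromosome 10 and chromosome 18 between 50900001 and 51000000 held 30 each.

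**Figure D4:**
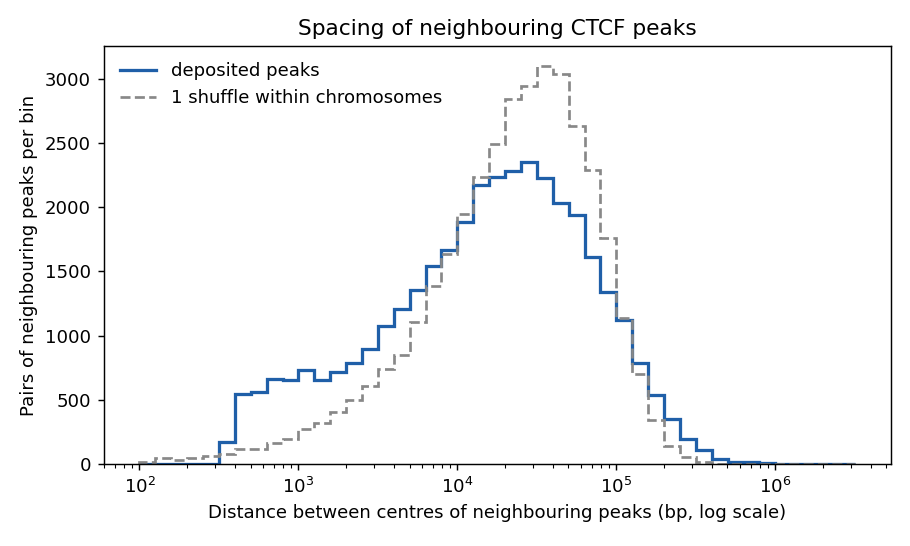
Number of pairs of neighbouring peaks (vertical axis) by the distance between their centres in bp (horizontal axis, log scale) for the deposited peaks (solid line) and for 1 shuffle within chromosomes (dashed line). The deposited peaks show a shoulder below 2 kb, where 12.9% of pairs lie, against 5.48% in shuffles within chromosomes. These shuffles do not keep the regional density.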

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

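All tests in this part were chosen after the data had been seen, and the share of low scores on chromosome 4 only after its result was known. The 1085 peaks on unplaced scaffolds lie outside every test above and show signal in sequence that the comparisons left out. They had a median score of 400 and a median width of 282 bp, against 368 and 263 bp on the chromosomes, and 13 of the 100 highest-scoring peaks of the list were among them.

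The concentration of peaks near chromosome ends was weighed against 3 technical explanations. Splitting of bound regions into several calls is argued against as the whole cause. Merging peaks within 10 kb lowered the mean ratio from 2.54 to 1.61, still above 1 in 25 of 25 chromosomes. Merging within 500 bp left 2.50. A merge within 10 kb can also join separate sites where peaks are dense, so the fall to 1.61 does not measure splitting. Background calls with low scores are argued against, because among the 9135 highest-scoring peaks the ratio rose to 3.48. This is another view of the higher scores near ends given above, and it does not address background that scores high. Sequence copies collapsed in the assembly remain open: they would raise scores near ends, and the median score there was at or below that of the rest in only 1 of 25 chromosomes, which stronger or more frequent occupancy near ends would also give. No biological explanation was tested, since gene density and base composition were not analysed here.

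The higher density of short chromosomes may reflect the larger part that dense ends make up of them. For sequence more than 10 Mb from both ends, without chromosome 4, Pearson's r of span and density was -0.434 (24 chromosomes, permutation p = 0.0348) and Spearman's rho was -0.503 (permutation p = 0.0135). Whole chromosomes without chromosome 4 gave r = -0.685. A relation thus remained in sequence more than 10 Mb from both ends. Mean density over all 25 chromosomes still fell there, from 23.5 per Mb at 10 to 15 Mb to 19.9 beyond 15 Mb. Short chromosomes hold less of the farthest sequence, so the cut cannot separate length from the same decline. In addition, r lay between the bounds set for the ends as the cause (weaker than -0.3) and not the cause (-0.5 or below). Spearman's rho reached the bound of -0.5. The share of the ends in the relation stays undecided.

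The scarcity of peaks on chromosome 4 between 31 and 70 Mb was weighed against calls lying just under the threshold. The share of this part in the lowest-scoring 25% of peaks was 1.5 times its share in the highest-scoring 25% (45 and 30 peaks, 95% interval 0.924 to 2.47), and the interval includes the bound of 2, so weak calls cannot be told apart from a lack of sites. Low scores were not particular to the sparse part, since the part from 70 Mb to the end, at 43.4 peaks per Mb, had a ratio of 1.71 (96 and 56 peaks) and a median score of 329, against 333.5 from 31 to 70 Mb. Low recovery of reads from sequence with many copies also stays open, because how well reads could be placed there was not analysed. Assembly gaps were not removed either. Any gaps in this part would lower its density as given and lengthen its intervals without peaks. The known heterochromatic state of this arm is an untested biological explanation.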

How the results depend on the processing

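The alternatives using the highest-scoring peaks and merging within 500 bp for the peak count, spacing and chromosome 4 results, and the arm taken from 40 Mb, were planned before the data were examined, and the others were chosen after seeing the data. Of 34 alternatives, 31 kept direction and side of the 0.05 threshold or, for the peak count, stayed within 1.5 times. Keeping only the highest-scoring peaks left 18270 by construction, and merging within 500 bp left 34202. The lower score rank of peaks with a neighbour within 2 kb turned to 0.117 percentage points above 50% (permutation p = 0.790) for neighbours within 5 kb; the cause was not tested. With 1 stretch per other chromosome the arm's 9.83 per Mb no longer passed (exact p = 0.118), because 16 chromosomes allow no smaller p. The median distance between neighbours stayed below its shuffled median under all 6 alternatives, the closest being 17520 against 18691 bp. The density on the chromosome 4 arm ranged from 4.22 per Mb for the highest-scoring peaks (13.99 elsewhere) to 10.7 per Mb from 40 Mb. The ratio of chromosome ends to the rest ranged from 1.61 to 3.48, with 2.94 for 1 Mb and 2.19 for 5 Mb at each end. The 95 settings planned for gene features, gene lists, motifs, repeats, Hox clusters and single replicates were not run, for want of sequence, annotation or values per replicate in the data used here. No paired analysis was possible because the peaks were called on combined replicates and the columns carry no replicate. The unknown depth limits what an absent peak means: a site missing from the list was not detected, not shown to be unbound.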

Other observations

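All comparisons in this part were chosen after the data had been seen. Closely spaced CTCF peaks were most over-represented at 500 to 750 bp between centres. That class held 1060 pairs, against 391 ± 17.5 (SD) in 100 shuffles within 100 kb bins, a ratio of 2.71. The ratio was 2.18 at 750 to 1000 bp, 1.89 at 1000 to 1250 bp and 1.31 at 1250 to 1500 bp, and at 2500 to 2750 bp it was 0.960. The excess within 500 bp is limited by the peaks' own widths of at least 200 bp and by the smallest gap of 101 bp. Merging peaks within 500 bp of each other lowered the peak count from 36540 to 34202. No shuffles within 100 kb bins were run on merged peaks. Close pairs at separate sites therefore cannot be told apart here from 1 bound region called as several peaks.

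Peaks with another peak within 2 kb, 8396 or 22.98% of those on chromosomes, had a median score of 359, against 371 for the others. They outranked the others in 47.9 ± 2.66% of pairs (SD, n = 25 chromosomes), below 50% in 18 of them (sign-flip permutation test, two-sided p = 0.00052). The departure from 50% was -4.01 percentage points for neighbours within 1 kb. For neighbours within 5 kb it was 0.117 and did not pass the test (permutation p = 0.790).

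The 80 peaks scoring above 2000 had a median width of 607 bp. Of these, 12 lay on unplaced scaffolds, 5 on chromosome 4, and 18 had another such peak within 10 kb.

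Scores were not spread evenly over whole numbers. The most frequent scores, 262, 273, 285, 296 and 308, lie 11 or 12 units apart. They were held by 282, 249, 303, 224 and 255 peaks, against medians of 71 to 103 peaks at the neighbouring scores.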
